A study of Oryza sativa with 3 samples.

How the data were processed

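RNA was measured in 3 shoot-tip samples of the rice cultivar Hitomebore on Affymetrix expression arrays, from 6 ug of total RNA labelled with biotin, per the labels' protocols. The labels call the samples biological replicates 1 to 3 of a single group, CK shoot, and do not spell out what CK stands for. Seeds were germinated in the dark for 2 days at 28 °C and kept about 48 h in a greenhouse at 26 °C with 16 h of light and 8 h of dark, per the labels' protocols. That protocol speaks of 2 genotypes, of which only Hitomebore is analysed here. How many plants went into a sample is not given in the sources used here.

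The values are log2 probe set values that the authors deposited after robust multi-array averaging (RMA) in Affymetrix Expression Console, per the submitters' processing notes. Versions and settings are not given in the sources used here. RMA subtracts background, quantile-normalizes the arrays and summarizes the probes of a set, so a difference in total RNA or overall brightness between samples is removed before deposit, and values near background are compressed. The sorted deposited values of the 3 arrays lay within 0.0980 log2 of their mean. RMA's summary also gives exact ties: 8.76% of probe sets held the same value on at least 2 arrays and 353 on all 3, so spreads near 0 are partly a product of the method. No scanner files were used.

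The table has 57381 probe sets, of which 123 are controls, left out of all tests. A platform annotation paired 22436 probe sets with 1 gene, 95 with several and listed no gene for 34850. Only the first kind was given a gene, which made 17905 genes, and names came from that annotation and the gene symbols and synonyms of assembly ASM3414082v1. The array's own genome build is not given in the sources used here, so no coordinates are printed. For a gene with several probe sets, the one with the highest mean was used.

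Gene lists were fixed as 235 loci before the data were examined. The annotation holds neither their locus identifiers nor product names, so loci were matched by symbol, chromosome and order along it: 128 were used, 77 had no symbol match, 17 had no probe set, 5 matched several genes, and 8 were contradicted by position, 6 by chromosome and 2 by order. Of these 8, PSAG entered the photosynthesis list through a symbol pattern. The product-name patterns fixed with them were rewritten as symbol patterns, and kinesins, aquaporins and growth-regulating factors were added as 3 lists, after the tables were seen and before any gene's level was looked at. The light-harvesting, photosystem and Calvin cycle lists were merged into photosynthesis. Of their fixed loci only PSAH, PETE, RCA and RPE were used, and no light-harvesting locus matched. The other photosynthesis genes came from symbol patterns. This left 24 lists of at least 3 genes, and a housekeeping pair. There were 2 genes that stood in 2 lists. List names are short labels: the seed storage list also holds WX, a starch synthase gene, and the cellulose synthase list CSLF6, a cellulose synthase-like gene.

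Agreement was measured as Pearson's r across probe sets, the median absolute difference and the SD per probe set. Spread above the trend was tested with limma 3.58.1 in R 4.3.3, with an intercept-only fit, trended and robust eBayes, an F test of each variance over its prior, and Benjamini-Hochberg adjustment at 0.05. The same fit gave the 95% interval of each mean. For lists, a gene permutation was used: the median of the list's mean levels, of its SDs, or of an array's value minus the mean of the other 2 arrays was placed among 100000 random gene lists. Random lists matched the number of probe sets per gene for levels and the tenth of mean level for SDs and array shifts. The p-values are two-sided, the smallest possible is 2e-05, and they were adjusted over 24 lists, or over 72 list and array pairs for shifts. These p-values describe these arrays. Genes are not replicates, and co-regulated genes make such p-values too small. An array set against the other 2 of its own group is not a comparison of conditions.

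Brightness depends on probe affinity as well as on RNA, so the test of list level and the naming rule by means describe array signal and do not rank RNA amounts between genes or lists. The highest of the 17 Tag control probe sets on each array, chosen after seeing the data, was taken as a ceiling of background. A fold against a value below it uses the ceiling and is written as at least that fold. Genes were named by a rule: per list the 3 highest means, the lowest mean and the highest SD, and over all named genes the 10 highest means and 10 highest SDs among genes above the array median on all 3 arrays. Of these 126 genes, 30 are given with values in the main account, and 3 others there (GLUA1, GLUB5, DREB1A) were chosen after their values were seen. Besides these, GLUA2 of the same rule is given for its probe sets, and the housekeeping pair, GAPC1 and ACT1, as the result of its list, of which ACT1 falls outside the rule.

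The methods were tested on simulated data. Among 17905 genes, lists of 6, 10 and 25 genes with 1 array raised by 0.3 log2 were called in 77.5%, 100.0% and 100.0% of 40 runs, lists raised in level by 3.0 log2 in 65.0%, 80.0% and 100.0%, and lists with added spread of 0.4 log2 in 95.0%, 100.0% and 100.0%. Unchanged lists of these sizes were called in 0.0% to 5.0% of tests. The simulated lists were drawn at random, so co-regulated genes were not tested. The variance test over 57258 probe sets recovered 0% of 200 probe sets at 3 and 6 times their spread and 2% at 10 times. It therefore has almost no power with 3 arrays. Alternatives were each replicate left out, arrays centred on their median, quantile normalization, only probe sets above the array median, probe sets ending in _x_at or _s_at left out, other limma priors, the mean of a gene's probe sets, and the locus lists alone. Array shifts against 1 other array, and array shifts with values below the background ceiling set to it, with and without _x_at and _s_at probe sets, were added after seeing the data. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used. The number of arrays limits the precision of all values.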

Results

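Expression was measured on 3 arrays, each with RNA of a shoot-tip sample from young Hitomebore seedlings, a temperate japonica rice cultivar. All 3 belong to the group CK shoot, so the design holds no contrast between conditions. The questions it can answer are which gene groups gave signal above background in this tissue and how far the samples agreed. The median log2 value over non-control probe sets was 4.91, 4.92 and 4.87 on replicates 1, 2 and 3. The highest Tag control probe set, used as a ceiling of background, read 4.98, 4.88 and 4.97. On all 3 arrays, 26786 of 57258 probe sets (46.8%) lay above it, as did 14556 of 17905 genes (81.3%).

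Ribosomal protein, photosynthesis, histone H2B, chlorophyll synthesis, cellulose synthase and auxin response genes gave signal well above background in the shoot tip. Their probe sets were brighter than random lists, which depends on probe affinity as well as on RNA and ranks no amounts. All 25 ribosomal protein genes lay above the background ceiling on every array, with a list median of 13.50 against 6.95 to 9.48 for the central 95% of random lists. Photosynthesis genes had a median of 12.11 (random lists 6.14 to 9.98), with 9 of 10 genes above the ceiling. Most genes of this list came from symbol patterns rewritten after the tables were seen, and few from the loci fixed in advance. Histone genes, here 5 genes of histone H2B, all lay above it, with a median of 12.62 (4.53 to 10.48). Cellulose synthases, 9 of 10 above the ceiling, had a median of 11.07 (6.12 to 9.98), chlorophyll synthesis genes, 6 of 6 above it, 11.34 (5.32 to 10.26) and auxin response genes 9.56 (7.18 to 9.14).

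These 6 lists lay above random lists in the gene permutation, with adjusted p-values of 0.00016 for ribosomal proteins and photosynthesis, 0.00084 for histones, 0.0040 for cellulose synthases and 0.0075 for chlorophyll synthesis and auxin response. RPS21 (LOC4332813), a protein of the small ribosomal subunit, read 14.19 ± 0.02 (SD, n = 3). LHCP (LOC4333359) and CAB2R (LOC4324599), light-harvesting chlorophyll-binding proteins, read 14.01 ± 0.09 and 13.82 ± 0.17 (SD, n = 3), and PETE (LOC4339833), plastocyanin, 13.99 ± 0.12 (SD, n = 3). PORA (LOC4337415), a protochlorophyllide reductase, read 12.16 ± 0.09 (SD, n = 3). H2B.5 (LOC4324504) read 12.76 ± 0.11, and CESA1 (LOC4337958), a cellulose synthase catalytic subunit, 12.67 ± 0.01 (SD, n = 3). Of 43 auxin response genes, 40 lay above the ceiling on all arrays, and IAA13 (LOC4334069), an Aux/IAA repressor, read 13.40 ± 0.06 (SD, n = 3). With the mean of all probe sets of a gene, cellulose synthases (9.32, adjusted gene permutation p = 0.064) and chlorophyll synthesis (9.90, adjusted p = 0.079) were no longer past the threshold.

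Most floral, alpha-amylase, root transporter, seed storage and defence genes did not lie above background on all 3 arrays. Of 34 floral MADS and flowering time genes, 24 lay below the ceiling on all 3 arrays, and the list median was 4.16 (random lists 6.97 to 9.21, adjusted gene permutation p = 0.00016). All 5 alpha-amylase genes, which act in the aleurone and scutellum of germinating grain, lay below it (median 3.88, adjusted p = 0.0075). Root transporters had a median of 4.07 (adjusted p = 0.0075), with 4 of 6 genes below the ceiling. Seed storage protein genes had a median of 4.74 (adjusted p = 0.0092) and defence genes 4.15 (adjusted p = 0.0060), with 1 of 9 and 1 of 8 genes above the ceiling on all arrays. Other stress genes were split: 11 of 22 heat shock genes lay above it on all arrays and 9 below (median 5.17, adjusted p = 0.0017), as did 4 and 3 of 8 dehydrins and LEA genes and 3 and 1 of 6 cold and fermentation genes.

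Single members of these lists were well above background. NRAMP5 (LOC4342859), a manganese transporter known from roots, read 9.96 ± 0.07 (SD, n = 3). MADS22 (LOC4330805), a MADS-box factor, read 8.72 ± 0.14, and HSFA2C (LOC4348646), a heat stress transcription factor, 10.60 ± 0.18 (SD, n = 3). PBZ1 (LOC4352491), a pathogenesis-related protein, read 8.73 ± 0.32 (SD, n = 3). The call for heat shock was lost with the locus list alone (5.21, adjusted gene permutation p = 0.081), and that for seed storage proteins without _x_at and _s_at probe sets (4.74, adjusted p = 0.061).

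The other 12 lists did not pass the test of level. Among them, 18 of 20 cell division genes and 31 of 32 kinesins lay above the ceiling on all arrays, with list medians of 9.08 and 8.72. PCNA (LOC4331062), the sliding clamp of DNA replication, read 11.33 ± 0.09, and KIN13B (LOC4326684), a microtubule motor protein, 10.45 ± 0.13 (SD, n = 3). Medians were 10.07 for circadian clock genes, 9.92 for YABBY factors, 8.91 for growth-regulating factors, 8.63 for expansins and 8.16 for aquaporins. They were 7.68 for gibberellin genes, 7.12 for cytokinin response regulators, 5.95 for KNOX and meristem genes, 5.88 for cold and fermentation genes and 5.67 for dehydrins and LEA genes. GI (LOC4325329), the clock gene GIGANTEA, read 11.41 ± 0.15, and YAB6 (LOC4352818), a YABBY family gene, 12.20 ± 0.16 (SD, n = 3). DL (LOC4332058), the YABBY gene of midrib and carpel, read 4.96, 5.70 and 5.71 on replicates 1, 2 and 3. TIP1-1 (LOC4331608), a tonoplast water channel, read 14.34 ± 0.09, EXPB3 (LOC4349349), a cell wall loosening beta-expansin, 13.60 ± 0.07, and HOS58 (LOC4328520), a KNOX homeobox gene, 11.37 ± 0.03 (SD, n = 3). The housekeeping pair, GAPC1 and ACT1, read 14.09 and 13.79.

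**Figure D1:**
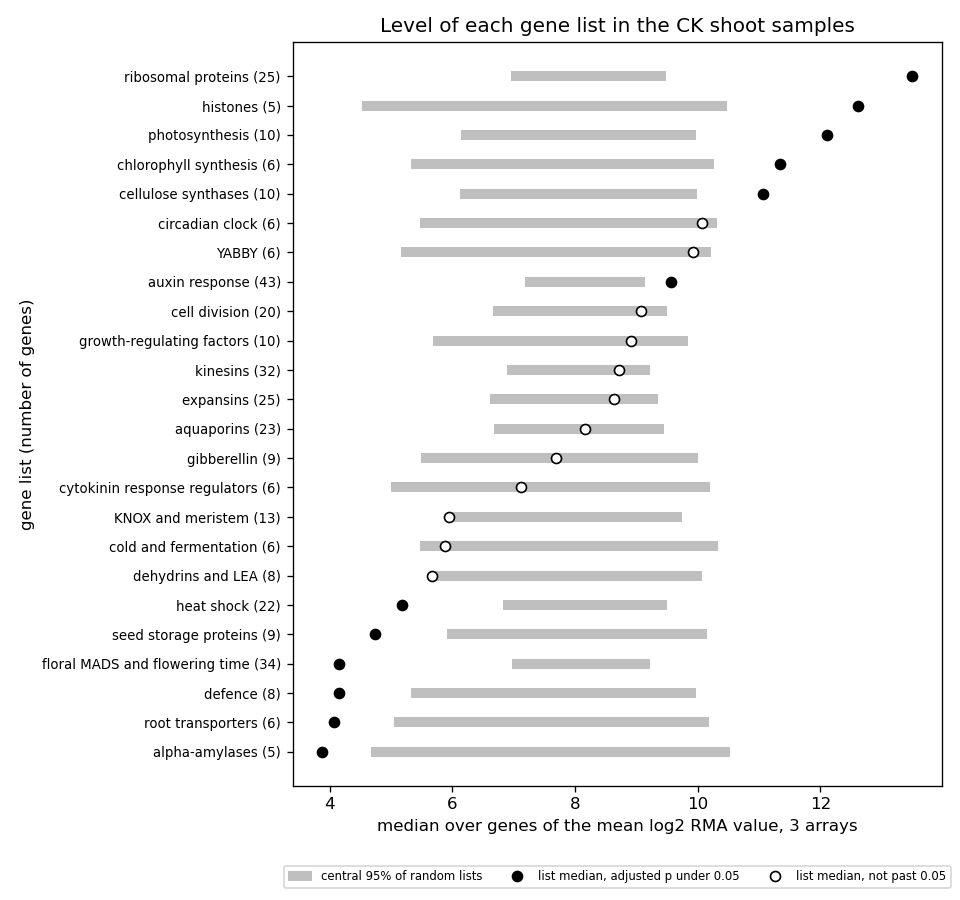
Median level of each gene list (x axis, log2 RMA value averaged over 3 arrays; number of genes in brackets) with the central 95% of random lists as grey bars. Filled points passed an adjusted p of 0.05, with a list median of, for example, 13.50 for ribosomal proteins; the values are array signal and do not rank RNA amounts.

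The 3 samples agreed closely over the whole array. Pearson's r across probe sets, which are not independent replicates, was 0.996 for replicates 1 and 2, 0.993 for 1 and 3, and 0.994 for 2 and 3. The median absolute difference was 0.12, 0.15 and 0.14 log2, and 88, 314 and 250 probe sets differed by over 1 log2. The median SD per probe set was 0.12 and its 99th percentile 0.49. In limma's variance test, 0 of 57258 probe sets passed an adjusted p of 0.05, against 1393 at an unadjusted p under 0.05, and 20 passed among the 27238 probe sets above the array median. On simulated data this test found 2% of probe sets even at 10 times their spread, so it cannot show that a gene did not vary, and differences of single genes below did not pass it over all probe sets. Among those above the array median, RAB21 (adjusted p = 0.024) and OsC3H37 (adjusted p = 0.031) passed, alone of the genes in the lists or given by the naming rule. The RAB21 probe sets that passed stood apart on replicate 1, and all other probe sets that passed stood apart on replicate 3. Several of the latter belong to LOC4340083, a gene that the naming rule did not give.

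Of 24 gene lists, 6 passed the test of spread, and most of these calls changed with the processing. Seed storage, cold and fermentation, YABBY and cell division genes had median SDs of 0.52, 0.47, 0.22 and 0.16, above random lists (adjusted gene permutation p = 0.00048, 0.00048, 0.035 and 0.044). Auxin response and ribosomal protein genes had median SDs of 0.08 and 0.05, below random lists (adjusted p = 0.047 for both). The remaining 18 lists did not pass. Without replicate 2 the median SD of seed storage genes was 0.13 (adjusted p = 0.69), and without replicate 3 that of cold and fermentation genes 0.14 (adjusted p = 0.53), while YABBY and cell division passed only when replicate 1 was left out. Calls for auxin response and ribosomal proteins were lost whichever replicate was left out. The number of lists that passed was 1 without _x_at and _s_at probe sets, where seed storage genes had 0.24 (adjusted p = 0.13), and 2 each when quantile normalized, above the array median, where cold and fermentation genes had 0.25 (adjusted p = 0.11), or with the mean of all probe sets.

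Replicate 2 had higher seed storage and photosynthesis genes and lower cell division genes and kinesins than the other 2 samples. Seed storage genes were higher by a median of 0.87 log2, with 8 of 9 genes highest on this array (adjusted gene permutation p = 0.00036). As 4 of the 9 genes lay below the background ceiling on all arrays, the shift was also taken with values below it set to it, and was then 0.30 (adjusted p = 0.00036). Without _x_at and _s_at probe sets as well it was -0.09, the value of random lists (adjusted p = 1.0), as 4 of the 7 genes left lay below the ceiling on all arrays. RAG2 (LOC4342723), a seed allergen protein of the grain, read 9.22 on replicate 2 against 4.40 and 3.94 on replicates 1 and 3, at least 19.0-fold higher, and PROLAMIN (LOC4342688), an endosperm storage protein, 8.32 against 5.31 and 4.73, at least 9.08-fold higher. The glutelin genes GLUA1 (LOC4327027) and GLUB5 (LOC4328968) read 6.61 and 6.63 on replicate 2, at least 3.11-fold and 3.14-fold higher. The differences of RAG2, PROLAMIN and GLUA1 were read only from probe sets ending in _x_at or _s_at, which can bind transcripts of several family members, and that of GLUB5 was not. The other RAG2 probe set, with the letter A in its ID, read 5.39, 5.41 and 5.14, and GLUA2 read 4.59, 7.30 and 5.09 from an _x_at probe set but 6.75, 7.21 and 7.07 from its other one.

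Photosynthesis genes were higher on replicate 2 by a median of 0.20, 9 of 10 being highest there (adjusted gene permutation p = 0.00072). Cell division genes were lower by 0.20, with 13 of 20 lowest (adjusted p = 0.00041), and kinesins by 0.21, with 26 of 32 lowest (adjusted p = 0.00036). Cold and fermentation genes were lower by 0.58 (adjusted p = 0.00041). The defence list also passed, with a shift of 0.19 (adjusted p = 0.030), but 5 of its 8 genes lay below the ceiling on all arrays, and the call was lost with such values set to the ceiling (adjusted p = 1.0) and among probe sets above the array median (0.09, adjusted p = 0.55). The KNOX and meristem list did not shift on replicate 2 (median -0.02, adjusted p = 0.99), yet OSH1 (LOC4333973), the homeobox gene of the indeterminate shoot meristem, read 3.73 there against 6.25 and 6.47, at least 2.79-fold lower. Its second probe set read 4.44 against 5.76 and 5.76. OSH71 (LOC4337701), another KNOX gene, read 4.93 against 6.67 and 6.24, 2.87-fold lower. With the locus list alone the cell division shift was -0.13 (adjusted p = 0.25), and against replicate 1 alone the cold and fermentation shift was -0.11 (adjusted p = 0.24) and the defence shift 0.20 (adjusted p = 0.086).

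Replicate 3 had higher cold and fermentation genes than either other sample, and higher cell division and kinesin genes than replicate 2. The latter 2 lists did not pass against replicate 1 alone, as given below. A gene's 3 shifts sum to 0, so a low replicate 2 alone raises the shift on replicate 3. Cold and fermentation genes were higher by a median of 0.79, with 5 of 6 highest on this array (adjusted gene permutation p = 0.00036). PDC1 (LOC4339066), a pyruvate decarboxylase of ethanol fermentation, read 9.41 against 4.04 and 3.95, at least 22.2-fold higher. ADH2 (LOC4350054), an alcohol dehydrogenase, read 9.76 against 8.90 and 8.55, 2.05-fold higher, and DREB1A (LOC4347620), a cold-responsive transcription factor, 6.14 against 4.31 and 4.17, at least 2.31-fold higher. Cell division genes were higher by 0.25, with 15 of 20 highest (adjusted p = 0.00041), kinesins by 0.20, with 27 of 32 highest (adjusted p = 0.038), and YABBY genes by 0.29, with 4 of 6 highest (adjusted p = 0.0080). Random lists matched on level were themselves higher there, by a median of 0.10 for kinesins, 0.06 for cell division and 0.05 for YABBY, so only the rest is particular to these lists. The YABBY call was lost without _x_at and _s_at probe sets (0.15, adjusted p = 0.38) and with the mean of all probe sets (0.20, adjusted p = 0.22).

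Photosynthesis genes were lower on replicate 3 by 0.16 (adjusted gene permutation p = 0.012). Cellulose synthases (0.14, adjusted p = 0.048), dehydrins and LEA genes (-0.18, adjusted p = 0.013) and seed storage genes (-0.26, adjusted p = 0.0027) also passed, but not with values below the background ceiling set to it (adjusted p = 0.11, 1.0 and 1.0). On the same array the ribosomal RNA control probe sets (18S, 25S and 28S) differed by a mean of -2.30 log2 (4.94-fold lower), and hybridization controls by 1.54-fold. Against replicate 1 alone, the shifts on replicate 3 of cell division (0.17), kinesins (0.13), photosynthesis (-0.10), YABBY (0.11) and seed storage (0.09) did not pass (adjusted p = 0.12, 0.65, 0.33, 0.60 and 0.96), nor did YABBY (0.22), cellulose synthases (-0.00035) and dehydrins and LEA genes (-0.03) against replicate 2 alone (adjusted p = 0.14, 0.69 and 0.45). With probe sets above the array median alone, 3 cold and fermentation genes were left, with a shift of 0.35 (adjusted p = 0.084), and with the locus list alone the cell division shift was 0.07 (adjusted p = 0.78).

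Replicate 1 stood apart in fewer gene groups. Expansins were higher by a median of 0.10, with 15 of 25 highest (adjusted gene permutation p = 0.0054), and EXPA29 (LOC4342086) read 8.42 against 7.36 and 7.71. Cellulose synthases were lower by 0.17, with 8 of 10 lowest (adjusted p = 0.0021), and seed storage genes by 0.61 (adjusted p = 0.00036). Dehydrins and LEA genes did not pass on this array (median 0.10, adjusted p = 0.066). In that list RAB21 (LOC4350454) and RAB16B (LOC4350453), dehydrins induced by abscisic acid, read 10.33 against 6.57 and 6.55, 13.7-fold higher, and 7.62 against 5.80 and 5.64, 3.74-fold higher. LEA3 (LEA19), a late embryogenesis abundant protein, read 11.11 against 10.51 and 10.42. The seed storage shift was -0.09 against replicate 3 alone (adjusted p = 0.96) and, with values below the ceiling set to it and without _x_at and _s_at probe sets, 0.06 (adjusted p = 1.0), and expansins did not pass against either array alone (0.05 on both, adjusted p = 0.13 and 0.30) or with values below the ceiling set to it (0.06, adjusted p = 1.0). Without _x_at and _s_at probe sets as well, expansins did pass, at 0.07 (adjusted p = 0.00058) against a median of 0.04 for random lists. The central range of these random lists ended at 0.06, the difference between the arrays' ceilings, so expansins lay only just above it. The expansin call therefore depended on the setting.

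**Figure D2:**
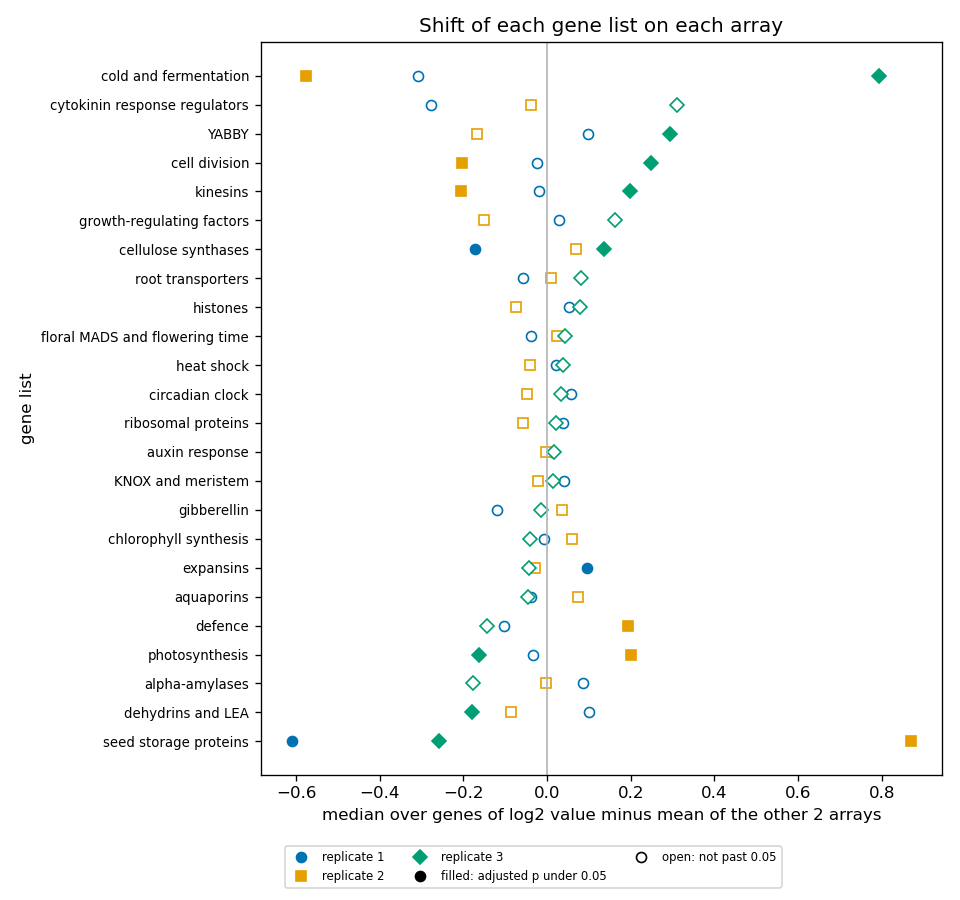
Shift of each gene list on each array (x axis, median over genes of the log2 value minus the mean of the other 2 arrays), with filled symbols where the adjusted p was under 0.05. Seed storage genes lay at 0.87 on replicate 2, and cold and fermentation genes at 0.79 on replicate 3.

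**Figure D3:**
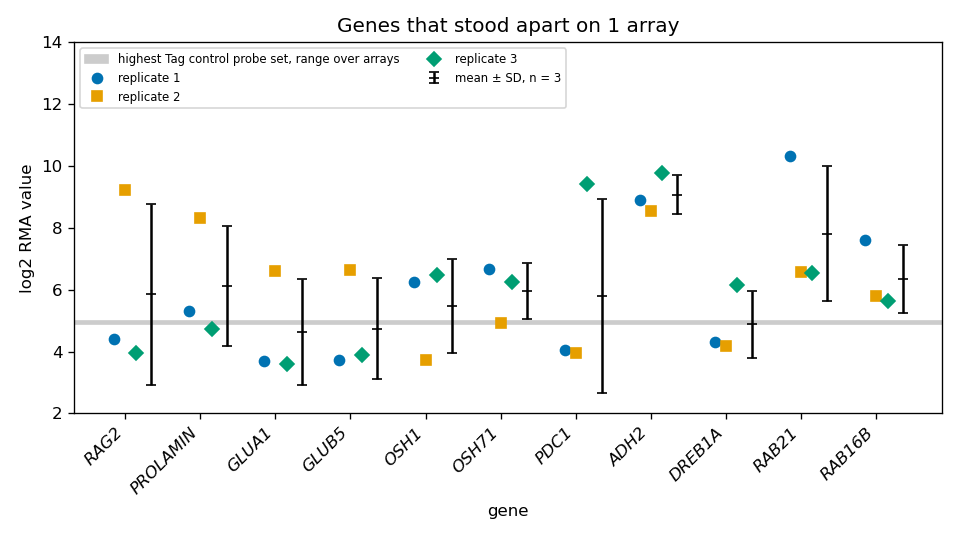
Log2 RMA values of 11 genes on the 3 arrays, with the mean and SD (n = 3) as black bars and the range of the background ceiling over arrays as a grey band. PDC1 reached 9.41 on replicate 3, RAG2 9.22 on replicate 2 and RAB21 10.33 on replicate 1.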

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

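All tests in this part were chosen after the results they bear on had been seen. With a single group, no biological explanation was tested.

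A signal outside the main measurement stood out in 4 of the 5 ribosomal RNA control probe sets, those for 18S, 25S and 28S RNA, which lay above the background ceiling on all arrays: they averaged 12.05, 11.73 and 9.59 on replicates 1, 2 and 3, a change of -2.30 on replicate 3, while that for 5.8S RNA read 5.60, 4.98 and 4.36. The hybridization controls changed by -0.63 there, and the ribosomal RNA change was -1.68 beyond theirs (standard error 0.34). That error is the scatter over probe sets, several of which read the same RNA, and not over samples. As RMA removes differences in overall brightness before deposit, these values cannot gauge how strongly the array hybridized. For the same reason, a uniformly weaker hybridization could not by itself lower these probe sets against the rest of the array. Weaker hybridization that differs between probe sets stays open and was not tested. Of the 28 other probe sets lower on replicate 3 by over 1 log2, 19 (67.9%) carried in their ID the letter A, against 7.48% of all probe sets (Fisher's exact test, two-sided p = 1.37e-15). This test treats probe sets of the same arrays as independent, which they are not. If that letter marks antisense orientation, which the sources used here do not give, less labelled RNA of the opposite strand on this array is a hypothesis for these 19 probe sets. The IDs of the ribosomal RNA controls do not carry the letter in this way, so whether it extends to them was not tested.

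Cold and fermentation genes were higher on replicate 3. The difference between 3' and 5' probe sets of actin, GAPDH, cyclophilin and ubiquitin exceeded that on the other arrays by a mean of 0.0482 (standard error 0.0269 over 4 transcripts). This argues against strongly degraded RNA, with 2 limits. Ubiquitin differed by -0.0956, -0.0684 and -0.0735 on replicates 1, 2 and 3, so it can show little. The 5' probe sets of the poly-A controls dap, lys and phe were highest on replicate 3, as given below, so some degradation could be masked. Normalization between arrays moves genes of the same level alike, but with values below the background ceiling set to it the shift was 0.69, against -0.06 to 0.23 for the central 95% of random lists matched on level (adjusted gene permutation p = 0.00036), which argues against it as the whole cause. A difference in how this sample grew or was handled stays open and was not tested.

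Seed storage genes were higher on replicate 2. Without _x_at and _s_at probe sets the shift was 0.30 (adjusted gene permutation p = 0.0069), and GLUB5, a gene chosen after its values were seen, read 6.63 against 3.71 and 3.89 from a probe set of neither kind. As 4 of the 7 genes left lay below the background ceiling on all arrays, this does not exclude probe sets that bind several family members, which stay open. RNA of germinating grain in the sample also stays open: the alpha-amylase list shifted by -0.0032, but all 5 of its genes lay below the background ceiling on every array, where a small share cannot be seen.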

How the results depend on the processing

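Comparisons with 1 other array, and those with values below the background ceiling set to it, were chosen after the results were seen. No paired analysis was possible because there is a single group. The 12 calls on list level kept their direction under all alternatives run, and their number was 12 without each replicate, centred or quantile normalized, 11 without _x_at and _s_at probe sets, 10 with the mean of all probe sets and 8 with the locus list alone, where 3 of the lists had no loci to test. Calls were lost for cellulose synthases (9.32) and chlorophyll synthesis (9.90) with the mean of all probe sets, heat shock (5.21) with the locus list alone and seed storage proteins (4.74) without _x_at and _s_at. The filter on dim probe sets was not run for list level. The cause of these changes was not tested, except that fewer arrays or genes enter some.

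Leaving out 1 replicate gave a median SD of 0.087 to 0.107, a mean r of 0.993 to 0.996 (0.991 above the array median) and 0 probe sets past limma's variance test, against 20 among probe sets above the array median. An SD over 2 arrays has a lower median than one over 3, so the lower median SD does not by itself show closer agreement. The list SDs without 1 replicate were set against random lists on the same 2 arrays. The lists called on spread numbered 6, and 1 to 5 without 1 replicate, 2 quantile normalized, 2 above the array median, 1 without _x_at and _s_at and 2 with the mean of all probe sets. Without 1 replicate, median SDs ranged from 0.133 to 0.231 for YABBY, 0.0583 to 0.0847 for auxin response (turned without replicate 3), 0.0934 to 0.212 for cell division, 0.142 to 0.602 for cold and fermentation, 0.0362 to 0.0580 for ribosomal proteins and 0.125 to 0.698 for seed storage. Calls were lost at these median SDs. Quantile normalized: YABBY 0.206, auxin response 0.0852, cell division 0.127, ribosomal proteins 0.0520. Above the array median: auxin response 0.0798, cell division 0.162, cold and fermentation 0.246, ribosomal proteins 0.0486. Without _x_at and _s_at: YABBY 0.210, auxin response 0.0820, cell division 0.174, ribosomal proteins 0.0534, seed storage 0.237. Mean of all probe sets: YABBY 0.210, auxin response 0.0834, cell division 0.159, ribosomal proteins 0.0657. Centred: ribosomal proteins 0.0668. Locus list alone: cell division 0.0920, turned to just below random lists.

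Array shifts past the threshold numbered 17, and 6 to 14 with 1 replicate left out, where each list counts once for either array of the pair. Those shifts ranged on replicate 3 from 0.113 to 0.218 for YABBY, 0.168 to 0.299 for cell division, -0.00035 to 0.200 for cellulose synthases (turned without replicate 1), -0.172 to -0.0264 for dehydrins and LEA, 0.132 to 0.256 for kinesins, -0.209 to -0.0971 for photosynthesis and -0.753 to 0.0919 for seed storage. On replicate 2 they ranged from -0.851 to -0.113 for cold and fermentation and 0.205 to 0.227 for defence, and on replicate 1 from 0.0467 to 0.0518 for expansins and -0.987 to -0.0919 for seed storage (turned relative to random lists without replicate 2). Calls on replicate 3 were lost for cellulose synthases quantile normalized (0.108), above the array median (0.127), without _x_at and _s_at (0.136) and with the mean of all probe sets (0.121), for dehydrins and LEA quantile normalized (-0.129), without _x_at and _s_at (-0.0518) and with the locus list alone (-0.157), for YABBY without _x_at and _s_at (0.146) and with the mean of all probe sets (0.205), for cell division with the locus list alone (0.0732), and for cold and fermentation above the array median (0.347). On replicate 2 they were lost for cell division with the locus list alone (-0.125) and defence above the array median (0.0929). With values below the ceiling set to it, calls were lost for cellulose synthases on replicate 3 (0.109) and, at the value of random lists, for defence on replicate 2 (-0.0930), dehydrins and LEA (0.0374) and seed storage (0.0374) on replicate 3 and expansins on replicate 1 (0.0556), because such genes then carry only the difference between the arrays' ceilings. Without _x_at and _s_at probe sets as well, 10 shifts passed. Expansins on replicate 1 did (0.0663, against a median of 0.0398 for random lists), and YABBY on replicate 3 (0.159) did not. Seed storage on replicates 1 (0.0556) and 2 (-0.0930) took the value of random lists, fixed by 4 of its 7 genes below the ceiling. List spread was not repeated in this way. Calls were also gained: over all alternatives, results not called in the main run passed in 22 comparisons of array shift and 4 of spread. With 1 replicate left out, either array of a pair counts. Aquaporins on replicate 2, for example, passed with values below the ceiling set to it (0.0186 against -0.0855 for random lists, adjusted gene permutation p = 0.0435).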

Other observations

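Other genes given by the naming rule were ML (LOC4326471), the salt-induced lectin also called salT, at 14.68 ± 0.04, and BURP2 (LOC4338119) at 14.58 ± 0.06 (SD, n = 3). HSP81-3 (LOC4347405), an HSP90 chaperone, read 14.39 ± 0.05, LOX1.1 (LOC4334049), a lipoxygenase, 14.19 ± 0.08, and GOS2 (LOC4343445), a translation initiation factor, 14.13 ± 0.02 (SD, n = 3).

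Other named genes with a high SD follow. OsC3H37 (LOC4339379), a CCCH zinc finger gene, read 10.11 on replicate 3 against 7.21 and 7.28, 7.30-fold higher, and SMR1 (LOC4349289) 8.46 against 6.94 and 6.47, 3.37-fold higher. The trehalose phosphate phosphatase OsTPP7 (LOC4346885) read 5.35, 6.22 and 6.82 on replicates 1, 2 and 3, and OsTPP1 (LOC4330221) 8.00 on replicate 3 against 6.70 and 7.15. MEAL1 (LOC4334449) read 8.68 against 7.38 and 7.71. MT-1-4b (LOC4352582), a metallothionein, read 11.08 against 12.37 and 11.93, and Cht6 (LOC4329920), a chitinase, 6.87 against 8.13 and 7.81. None of these passed limma's variance test over all 57258 probe sets, and OsC3H37 did among those above the array median (adjusted p = 0.031).

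Replicate 3 had 117 probe sets above both other arrays by over 1 log2, of which 43 have no single gene here, and 28 below both. Replicate 1 had 20 above and 6 below, and replicate 2 had 30 above and 10 below. Poly-A control probe sets differed by 0.10 on replicate 3, on average over 36. This average hides that all 5' probe sets of dap, lys and phe were highest there, while those of thr were not. For example, a 5' probe set of dap read 5.31, 5.85 and 6.08 on replicates 1, 2 and 3. The 3' probe set of the same control read 11.18, 11.06 and 11.03.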
